A study of Mus musculus with 4 samples.

How the data were processed

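The experiment was a single-cell RNA-seq time course of mammary tumour formation in mice. Per the labels, female mice of mixed background carried floxed Trp53 and Brca1 alleles and a Rosa26 YFP reporter, and Cre was delivered into the milk ducts by an adenovirus with a keratin 8 promoter, which targets luminal cells. YFP+ cells were sorted about 2 weeks after injection (2 weeks library), YFP+ cells and CD45+ leukocytes were sorted about 5 months after injection (5 months library), and live DAPI-negative cells were taken from tumour masses (tumour 1 and tumour 2). Libraries were made with the Chromium Single Cell 3' v2 kit per the labels. Reads were processed with Cell Ranger against mm10 (GRCm38) per the submitters' processing notes, and the Cell Ranger version was not given in the sources used here. The deposited values were UMI counts per gene and cell barcode. The labels give neither the number of mice per library nor the ratio at which YFP+ and CD45+ cells were mixed.

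The libraries held 1453 (2 weeks), 4836 (5 months), 2712 (tumour 1) and 1780 (tumour 2) barcodes, with 6722044, 15060411, 23736366 and 13061942 UMIs. Median UMIs per barcode were 3876, 2162, 6972 and 6403.5, and median genes per barcode were 1503, 858.5, 1998 and 1929.5. Gene names of the premalignant libraries carried a genome prefix that was removed, and the 27998 gene names shared by the 4 libraries were used. A further 694 genes were listed for the 5 months library alone. They held 4.59% of its UMIs, most of them of immunoglobulin genes (Igkc 501733 UMIs, Igha 73346, Ighg2b 28399), and were left out because the other libraries have no value for them.

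Cells with at least 500 detected genes and at most 10% mitochondrial UMIs were kept (1301, 4668, 2640 and 1765). Doublets were scored with Scrublet in scanpy. Its automatic threshold called 4, 0, 0 and 8 doublets and was judged not to have worked, so the highest-scoring barcodes were removed at 0.8% per 1000 barcodes (15, 181, 57 and 25), a rule chosen after the scores were seen. This left 1286, 4487, 2583 and 1740 cells. Each library was grouped alone: counts scaled to 10000 per cell and log-transformed, 2000 variable genes, 30 principal components, 15 neighbours, Leiden at resolution 1.0, seed 1. This gave 11, 20, 19 and 16 clusters.

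Clusters were named by markers of 19 cell classes fixed before the data were examined. A class score was the mean over its markers of the cluster's level relative to the highest cluster of any library, and a class needed 3 markers detected in 10% of the cells. A cluster was left unnamed when its best score was under 0.5, when a second lineage reached 0.8 of the first, when its 10 leading genes held more markers of another class than of its own, or when it had few UMIs and no leading marker. Subclasses of epithelial-like and leukocyte-like cells were named by the same rules. Names therefore mean resemblance in RNA. Malignant and untransformed epithelial cells were not separated, and recombined and intact Trp53 or Brca1 alleles were not told apart. Shares of cells carry exact (Clopper-Pearson) binomial 95% intervals that hold counting error only. Reads, cell-free RNA models, integration across libraries and cell trajectories were not used here.

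UMIs were summed per library over the epithelial-like, macrophage- or monocyte-like and T cell-like cells; a leukocyte comparison needed 30 cells in every library, and the 2 weeks library held no named leukocyte-like cells. Only the tumours are replicates (n = 2). Tumour and premalignant libraries were compared with edgeR (filterByExpr, TMM factors, quasi-likelihood F test) in 1 fit with 3 groups for epithelial-like cells and 2 groups for leukocytes, with 1 residual degree of freedom, and p-values were adjusted over all tested genes by Benjamini-Hochberg at 0.05. The biological coefficient of variation was 0.428 for epithelial-like, 0.281 for macrophage- or monocyte-like and 0.338 for T cell-like cells. Every p-value of these fits rests on spread between the 2 tumour samples, estimated largely over many genes together. A gene can therefore pass although its own values in the 2 tumours lie far apart. A lone premalignant library was assumed to vary as the tumours do. A gene counted as higher or lower in a sample on the side that its TMM-scaled CPM gave.

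The 5 months and 2 weeks libraries, and tumour 1 and tumour 2, were each compared 1 against 1 with no p-value. A gene was counted when its TMM-scaled CPM lay at least 2-fold apart after adding 1 CPM, with at least 20 CPM in the higher library. Where a group had no counts, the ratio is given as at least the fold obtained with 3 counts over that group. Intervals on CPM are 95% Poisson intervals.

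A total of 26 gene lists of 7 to 27 members were fixed before any value was seen: epithelial junction and keratin, luminal progenitor and milk, hormone-sensing luminal, basal, mesenchymal, stem and neural crest, S phase, G2 and M phase, DNA repair and replication stress, p53 target, NF-kB and inflammation, interferon response, MHC class I presentation, MHC class II presentation, unfolded protein and integrated stress, hypoxia and glycolysis, oxidative phosphorylation, Notch, Wnt, senescence and secretory, dissociation and immediate early, leukocyte, T cell exhaustion and checkpoint, T cell cytotoxicity, regulatory T cell, and tumour-associated macrophage. For each list, members past the rule or test, the median log2 ratio, and the percentile of that median among 10000 random lists matched on mean level were computed. Values of some single list members are not reported here. Genes named per comparison were the 6 with the largest ratio in each direction at 100 CPM or more on the higher side, passing genes first and with the same direction in both tumours, without genes over 5 times higher in the other cell class of the same library, and without mitochondrial, Rpl, Rps, immunoglobulin and unnamed-transcript genes. Also named were members with the largest ratios in each list at 20 CPM or more. A gene over 5 times higher in leukocyte-like than in epithelial-like cells of the same library, or the reverse, is reported as such because free RNA can carry it between cells.

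Calls per cell were made after thinning each cell to 2000 UMIs, and cells with fewer were left out of them. Keratin co-detection meant at least 1 UMI of Krt8 or Krt18 and 1 of Krt5 or Krt14. A proliferating call meant at least 2 UMIs over the G2 and M phase list.

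Alternatives changed the normalization (DESeq2 size factors, library size only), test (DESeq2 Wald), low-count filter, group structure (premalignant libraries as 1 group), population, cell filter (200 genes and 20% mitochondrial UMIs; 1000 genes and 5%), doublet removal, resolution (0.5 and 2.0), pseudocount (5 CPM), CPM threshold (100 CPM) and thinning (1000, 3000, none). The 4 chosen after seeing the data were hormone-sensing cells only, leaving out ribosomal protein genes low at 2 weeks (for each comparison with that library), and leaving out macrophage genes for T cells.

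The tests were tested on simulated data. With 50 genes changed at each of 4-, 8-, 16- and 32-fold, edgeR recovered 24%, 66%, 92% and 100% against 2 weeks (7 unchanged genes called of 12064 tested) and 20%, 66%, 92% and 100% against 5 months (11 of 12073). Recovery was 54%, 98%, 98% and 100% in macrophages (5 of 8848) and 58%, 96%, 100% and 100% in T cells (13 of 6353). These edgeR simulations gave all genes and libraries of a comparison the same biological coefficient of variation. It was 0.4 in epithelial-like cells and 0.3 in macrophages and T cells. The counts of unchanged genes called therefore say nothing about premalignant libraries that vary unlike the tumours, or about spread that differs between genes. The 2-fold rule recovered 2% of genes at 1.5-fold and 100% at 3-fold, with 0 unchanged genes called. Libraries simulated for this rule differed by counting error only. The 0 therefore says nothing about genes called through spread between libraries. With edgeR, changes under about 8-fold in epithelial-like cells were often missed.

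Versions were Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scanpy 1.11.5, leidenalg 0.10.2, statsmodels 0.14.6, scikit-learn 1.9.0, matplotlib 3.10.9, R 4.3.3, edgeR 4.0.16 and DESeq2 1.42.0.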

Results

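Trp53 and Brca1, the genes targeted by Cre, were looked at first in epithelial-like cells of every library. Trp53, which encodes the p53 tumour suppressor, had 52.7 CPM (95% interval 46.9 to 59.0) at 2 weeks, 41.2 (33.3 to 50.3) at 5 months, 11.4 (8.92 to 14.5) in tumour 1 and 49.0 (42.6 to 56.0) in tumour 2. In leukocyte-like cells it had 134.6 CPM at 5 months, 30.1 in tumour 1 and 65.3 in tumour 2. Brca1, which encodes a homologous recombination protein, had 3.68, 0.87, 0.82 and 1.17 CPM in epithelial-like cells, from 21, 2, 5 and 5 UMIs. The deleted parts of these genes were not located relative to the 3' tags, so these values are not read as a check of deletion. Krt8, the keratin whose promoter drove Cre, had 2646, 2896, 1401 and 1072 CPM, and its partner Krt18 had 3538, 3636, 1710 and 1226 CPM.

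The question of the cell shares was which epithelial state the cells held as tumours formed. At 2 weeks, 81.7% (79.4 to 83.8) of epithelial-like cells resembled hormone-sensing luminal cells (clusters 0, 1, 2, 3, 7, 9 and 10), the lineage that carries hormone receptors. A further 13.1% (11.2 to 15.1, cluster 8) resembled luminal progenitor or alveolar cells, the lineage that makes milk, but this class held 0% with doublets kept, 0% at resolution 0.5 and 5.30% at resolution 2.0. Basal-like cells were 5.26% (4.06 to 6.69, cluster 4), although the endothelial genes Ackr1 and Selp also led that cluster. At 5 months the order was the reverse, with 90.5% (87.5 to 93.0, cluster 2) luminal progenitor- or alveolar-like and 9.47% (6.99 to 12.5, cluster 19) hormone-sensing-like cells. Basal-like cells were 0 of 475 (up to 0.774%). In tumour 1, 100% (99.1 to 100, clusters 2 and 3) of epithelial-like cells scored nearest to luminal progenitor or alveolar cells. None of that class's markers was among the 10 leading genes of either cluster when ranked against the clusters of all libraries. Ranked within tumour 1, the class's marker Csn1s1 led cluster 2, and its markers Wfdc18, Csn3 and Lcn2 were among the leading genes of cluster 3. In tumour 2 the class held 74.0% (69.7 to 78.0, clusters 2 and 4), and 26.0% stayed unnamed (clusters 6 and 7), each with 1 basal marker among its 10 leading genes. These intervals hold counting error only, and each time point is 1 library.

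**Figure D1:**
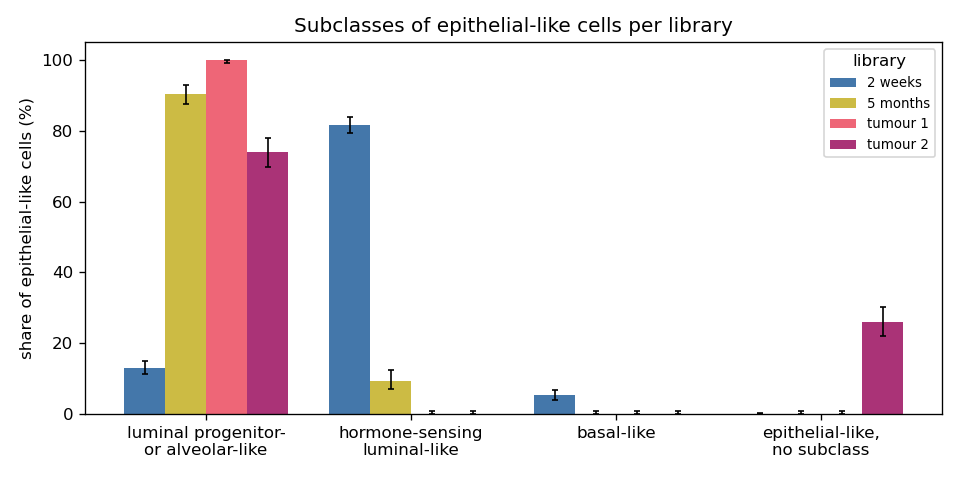
Shares of epithelial-like cells that resemble each mammary epithelial subclass in each library. Error bars are exact binomial 95% intervals, which hold counting error only.

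Shares over all cells are given with the sort of each library, because the sorts differed. The YFP+ sort at 2 weeks gave 91.7% (90.0 to 93.1, 1179 of 1286) epithelial-like and 0 of 1286 named leukocyte-like cells (up to 0.286%), although an unnamed cluster of 18 cells (cluster 5) scored for both lineages and was led within the library by the leukocyte genes Lyz2, Tyrobp and Cd52. The YFP+ and CD45+ sort at 5 months gave 10.6% (9.70 to 11.5, 475 of 4487) epithelial-like and 88.8% (87.8 to 89.7) leukocyte-like cells. Live cells gave 15.8% (14.4 to 17.3, 409 of 2583) epithelial-like and 76.2% (74.5 to 77.8) leukocyte-like cells in tumour 1, and 25.9% (23.8 to 28.0, 450 of 1740) and 52.2% (49.8 to 54.6) in tumour 2. Clusters with no named lineage held 8.32%, 0%, 2.75% and 22.0% of the cells of the 4 libraries, not counting leukocyte-like or epithelial-like clusters without a subclass. Fibroblast-like cells were 0.646% of cells at 5 months and 4.14% in tumour 1, where 1.08% were endothelial-like.

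Of 3983 leukocyte-like cells of the CD45+ sort at 5 months, 49.4% (47.8 to 51.0) were T cell-like, 16.2% B cell-like, 10.6% dendritic cell-like, 9.89% macrophage- or monocyte-like, 3.16% plasma cell-like and 10.7% unnamed. With the stricter cell filter these were 29.2% T cell-like, 6.39% B cell-like, 21.4% dendritic cell-like and 17.2% macrophage- or monocyte-like. Among live cells of tumour 1, 91.9% (90.6 to 93.1) of 1968 leukocyte-like cells were macrophage- or monocyte-like and 2.08% T cell-like, with 1.52% plasma cell-like and 4.47% unnamed. In tumour 2 the 908 leukocyte-like cells were split among macrophages or monocytes (30.9%, 28.0 to 34.1), T cells (19.2%, 16.7 to 21.9), neutrophils (18.9%), B cells (3.19%), plasma cells (1.43%) and unnamed cells (26.3%). The macrophage share of tumour 2 was not stable, with 47.1% to 56.1% under 4 of 5 other settings, and a cluster of 230 cells nearest to macrophages (cluster 0) was left unnamed over 1 dendritic cell gene. No share was tested between groups.

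Luminal and basal keratins were then looked for in the same cell. Epithelial-like cells thinned to 2000 UMIs carried both kinds in 3.70% (2.62 to 5.06, 37 of 1001, 178 left out) of cells at 2 weeks, 3.89% (2.28 to 6.16, 17 of 437, 38 left out) at 5 months, 15.2% (11.82 to 19.01, 62 of 409) in tumour 1 and 2.67% (1.39 to 4.61, 12 of 450) in tumour 2. At 2 weeks the call fell on 30.6% of basal-like, 13.4% of luminal progenitor- or alveolar-like and 0.606% of hormone-sensing-like cells. Leukocyte-like cells, where free RNA would show, carried it in 0 of 2008 cells at 5 months (1975 left out), 0.051% in tumour 1 and 0 of 908 in tumour 2. Median UMIs were 4553, 14536 and 7856.5 in epithelial-like and 2014, 6368.5 and 5199.5 in leukocyte-like cells of these libraries. Unthinned shares were 5.60%, 7.16%, 34.2% and 6.67% in epithelial-like cells of the 4 libraries. Krt14, a basal keratin, had 73.2, 84.5, 202 and 26.1 CPM, while Krt5 had 9.28 and 15.2 CPM in the premalignant libraries and 0 in the tumours (3 counts would be 0.49 and 0.699 CPM).

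The proliferating call was made in 48.0% (44.8 to 51.1, 480 of 1001) of thinned epithelial-like cells at 2 weeks, 9.15% (6.62 to 12.3, 40 of 437) at 5 months, 29.3% (25.0 to 34.0, 120 of 409) in tumour 1 and 23.8% (19.9 to 28.0, 107 of 450) in tumour 2. By subclass at 2 weeks it was 48.8% (39.9 to 57.8) of luminal progenitor- or alveolar-like, 48.1% (44.7 to 51.6) of hormone-sensing-like and 42.9% (28.8 to 57.8) of basal-like cells, with no test between them. Unthinned shares were 58.5%, 29.7%, 77.0% and 64.7%. Leukocyte-like cells carried the call in 34.3%, 20.6% and 26.4% at 5 months and in tumours 1 and 2. Their median was 2014 UMIs at 5 months, so thinning left out many of them there. Top2a was among the genes that led some leukocyte-like clusters within their library (clusters 8 and 16 at 5 months, cluster 11 in tumour 1). Leukocyte-like cells may thus cycle themselves, and their share does not measure free RNA. Free RNA stayed open as a source, and the call alone is not read as cycling.

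**Figure D2:**
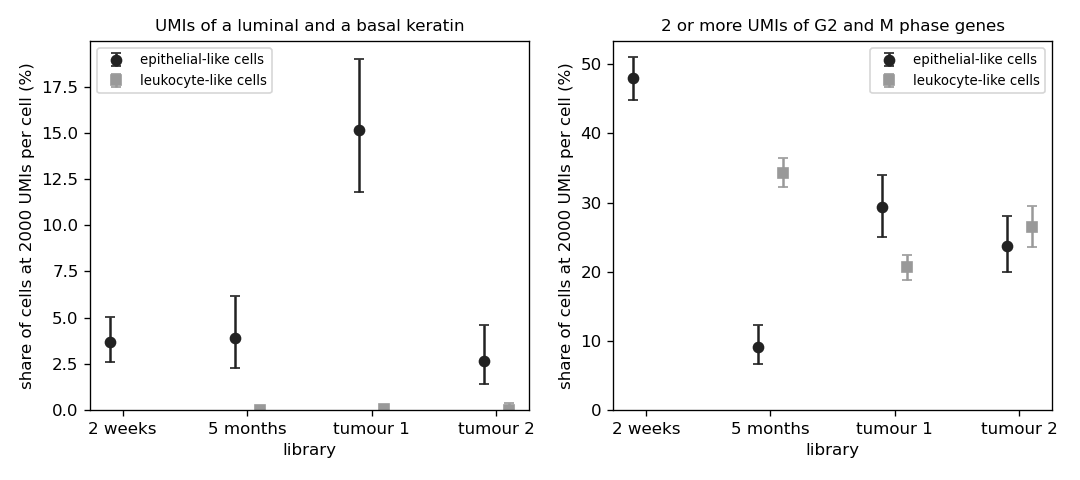
Shares of epithelial-like and leukocyte-like cells with UMIs of both luminal and basal keratins, and with the proliferating call, after thinning every cell to 2000 UMIs. Error bars are exact binomial 95% intervals, which hold counting error only.

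Between 2 weeks and 5 months, milk genes showed the largest differences in epithelial-like cells. The caseins Csn1s2a (21068 CPM, 20881 to 21256, against 21.7, 18.1 to 25.9, log2 ratio 9.86), Csn2 (19696 against 36.1, 9.05) and Csn1s1 (7.95) were far higher at 5 months. So were the lactose synthase subunit Lalba (9.27), the whey protein Wap (256 CPM against 0.18, 0.00 to 0.98, 1 count, 7.77) and the iron-binding milk protein Ltf (7.62). Of the luminal progenitor and milk list, 17 of 20 members were at least 2-fold higher and 0 lower (median 4.42, percentile 100 among random lists). Lower at 5 months were the urothelial plaque gene Upk3a (231 CPM, 219 to 244, against 0 counts) and the T cell attractant Cxcl9 (579 CPM, 559 to 599, against 3.03, 1.22 to 6.25, −7.17). The tryptophan-degrading enzyme Ido1 (130 CPM against 1.30, 0.27 to 3.80, −5.84), the fibrinogen chains Fgg (−5.41) and Fgb (−5.31), and the DNA topoisomerase Top2a (−5.62) were also lower. Hormone-sensing genes were lower, with 6 of 10 members lower and 0 higher (median −1.76, percentile 0). Among them were the transcriptional regulator Cited1 (−4.72), the progesterone receptor Pgr (−3.96) and its growth factor target Areg (−3.94).

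Cell cycle genes were lower at 5 months. The S phase list had 13 of 24 members lower (median −1.86, the nucleotide reductase Rrm2 −3.44, the DNA methylation cofactor Uhrf1 −3.15). The G2 and M phase list had 19 of 27 lower (−2.65, the mitotic ubiquitin enzyme Ube2c −4.44, the mitotic kinase Cdk1 −4.36), with 0 higher in either. DNA repair and replication stress had 4 of 20 members lower and 0 higher (−1.82). Interferon response had 6 of 19 lower and 0 higher (−0.59), among them the chemokine Cxcl10 (−3.72) and the antiviral membrane protein Ifitm3 (−2.07). MHC class I presentation had 3 of 12 lower and 0 higher (−0.68, the immunoproteasome subunits Psmb9 −2.21 and Psmb10 −1.79), and oxidative phosphorylation 1 of 16 and 0 (−0.49).

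Further lists had members higher and 0 lower at 5 months. Hypoxia and glycolysis had 9 of 18 members higher (median 1.46), among them the glucose transporter Slc2a1 (3.12), the hexokinase Hk2 (3.10) and the angiogenic factor Vegfa (2.98). Stem and neural crest had 4 of 7 higher (1.71), among them the neural crest factor Sox10 (3.70), the forkhead factor Foxc1 (2.18) and the secreted Sox10 target Mia (1.78). In hormone-sensing-like cells alone Sox10 had −0.56 and Foxc1 −0.77. Unfolded protein and integrated stress had 4 of 15 higher (0.40, the chaperones Dnajb9 3.29 and Hspa5 2.10), a median inside the random interval (−0.524 to 0.429), and 3 higher and 5 lower in hormone-sensing-like cells alone. Dissociation and immediate early had 10 of 14 higher (2.09, the early response genes Fosb 3.61, Ier3 3.51 and Dusp1 3.50), and such genes also respond to tissue dissociation.

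The remaining lists are given in turn for 5 months against 2 weeks. NF-kB and inflammation had 4 members higher and 3 lower of 17 (median 0.75, percentile 99.82, the neutrophil attractants Cxcl2 2.89 and Cxcl5 −4.61, the feedback inhibitor Tnfaip3 2.54). The p53 target list had 2 higher and 3 lower of 18 (−0.51, the survival regulator Phlda3 −2.26). Epithelial junction and keratin had 4 higher and 1 lower of 17 (0.13, the claudin Cldn4 2.32, the epithelial factor Ehf 1.79), and basal 1 and 1 of 16 (0.24, the keratin Krt15 −3.27). In luminal progenitor- or alveolar-like cells alone the basal list had 5 higher and 0 lower of 14 (3.14, percentile 100). Mesenchymal genes had 0 higher and 1 lower of 16 (−0.43, the fibrillar collagen Col3a1 −4.18), but the median was 2.00 in luminal progenitor- or alveolar-like (2 higher and 0 lower of 13) and 2.55 in hormone-sensing-like cells alone (0 and 0 of 6). MHC class II presentation had 0 and 1 of 6 (−0.22). The Notch list had 1 and 2 of 7 (0.16, the Notch target Hes1 2.21), Wnt 0 and 0 of 6 (0.97), and senescence and secretory 1 and 2 of 10 (0.06). All 8 leukocyte list members were higher at 5 months (4.69, the lymphocyte surface gene Cd52 5.12 with 1 count at 2 weeks). All 8 were over 5 times higher in leukocyte-like cells of the same library, from which free RNA can carry them. Lists of T cell exhaustion and checkpoint (0 and 0 of 6), T cell cytotoxicity (0 and 0 of 3) and regulatory T cell genes (0 and 0 of 5) had no member past the rule. The tumour-associated macrophage list had 2 higher and 0 lower of 9 (0.77, the matrix protein Spp1 7.50).

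In all, 1663 of 5804 genes were at least 2-fold apart, 860 higher and 803 lower at 5 months, of which 29 of the higher were over 5 times higher in leukocyte-like cells. Counts were 1479 of 5778 (917 higher, 562 lower) in luminal progenitor- or alveolar-like cells alone and 1781 of 6026 (699 higher, 1082 lower) in hormone-sensing-like cells alone. Within these subclasses the milk list had 17 of 20 and 8 of 16 members higher, interferon response 9 of 19 and 10 of 17 lower, and the G2 and M phase list 13 and 19 of 27 lower. Free milk RNA was not excluded in the hormone-sensing-like cells, as leukocyte-like cells of that library had 63.4 CPM of Csn2. Hypoxia and glycolysis had 9 of 18 higher in the former and 1 of 16 in the latter. The hormone-sensing list had 5 of 10 lower in the former, but 4 of 11 higher and 3 lower in the latter (median 0.98). With library size scaling alone the split was 755 higher and 1011 lower, and the median log2 ratio shifted from −0.046 to −0.151. The direction of moderate differences therefore depends on scaling. This was 1 library against 1 with no replicate check, and age, sort and library differ together.

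**Figure D3:**
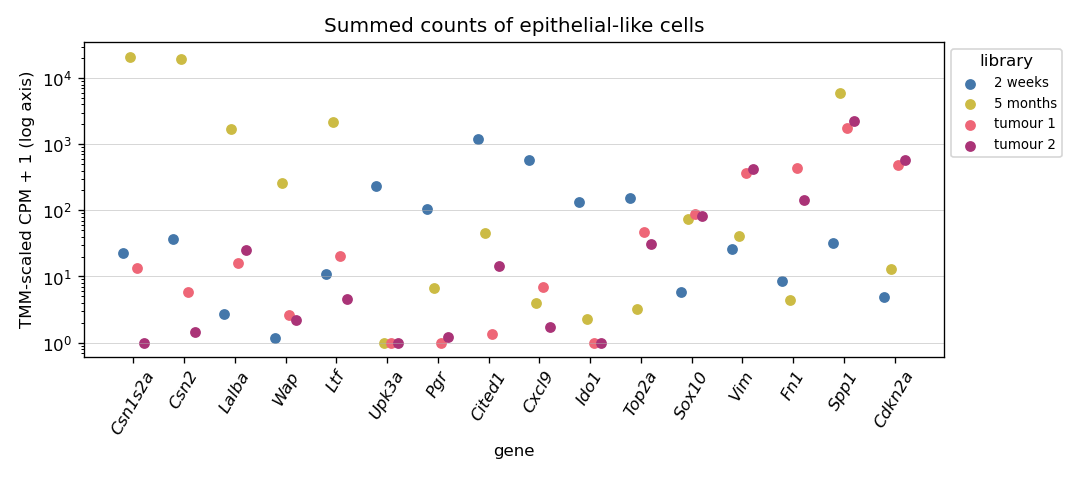
TMM-scaled CPM of named genes in the epithelial-like cells of each library, on a log axis with 1 CPM added. Each point is 1 library.

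Tumours were then set against 2 weeks cells. Cdkn2a, which encodes the cell cycle inhibitors p16 and p19Arf, rose from 3.85 CPM to 491 and 585 CPM (mean 538, SD 66.2, log2 7.10, SE 0.802, edgeR adjusted p = 0.00520, higher in 2 of 2 tumours). The collagens Col11a1 (6.85, SE 1.41, edgeR adjusted p = 0.0442) and Col9a1 (6.26, SE 0.952, adjusted p = 0.0141), the phospholipase Pla2g7 (6.46, SE 0.933, adjusted p = 0.0115) and the matrix protein Spp1 (5.97, SE 0.694, adjusted p = 0.00624) rose in 2 of 2 tumours as well. Fau, a ribosomal fusion gene, also rose (6.50, SE 0.690, edgeR adjusted p = 0.00431, 2 of 2 tumours) but was low in the whole 2 weeks library. Falling to 0 counts in 2 of 2 tumours (edgeR adjusted p at most 0.00364) were Upk3a (at least 803-fold), the secreted-protein gene R3hdml (at least 778-fold) and Ido1 (at least 453-fold). The epithelial chemokine Cxcl15 (at least 376-fold), Fgb (at least 373-fold) and the milk mucin Glycam1 (at least 276-fold) fell to 0 counts in 2 of 2 tumours at the same edgeR level.

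Hormone-sensing genes were lower in tumours: 8 of 11 members were at least 2-fold lower and 0 higher (median −3.80, percentile 0), and 7 of 10 tested passed edgeR over all genes (8 adjusted over the list alone). Pgr fell in 2 of 2 tumours (−9.69, SE 0.918, edgeR adjusted p = 0.00364, 1 count over both tumours against 583). So did Cited1 (1197 CPM to 0.327 and 13.5, −7.47, SE 1.35, edgeR adjusted p = 0.0273) and the prolactin receptor Prlr (−4.48, SE 0.545, adjusted p = 0.00713). In the epithelial junction and keratin list (0 higher, 1 lower over all genes, 0 and 1 adjusted over the list alone), the luminal keratin Krt19 fell in 2 of 2 tumours (−3.83, SE 0.51, edgeR adjusted p = 0.00887). The iron-binding gene Lcn2 of the milk list rose in 2 of 2 tumours (4.40, SE 0.612, edgeR adjusted p = 0.00977). That list had 4 members higher and 1 lower over all genes, and 10 and 2 adjusted over the list alone. Basal genes had 0 higher and 3 lower (1 and 6 adjusted over the list alone, median −1.45), but the median was 1.09 in luminal progenitor- or alveolar-like cells alone. Among them were the contractile genes Tagln (−4.85, SE 0.653, edgeR adjusted p = 0.00908) and Acta2 (−4.78, SE 0.615, adjusted p = 0.00831), each lower in 2 of 2 tumours, although Tagln had 1.499 in all cells that are not leukocyte-like. Both led the basal-like cluster of 62 cells within the 2 weeks library (cluster 4). That wider population also holds an unnamed tumour 1 cluster of 35 cells led by both genes (cluster 4). These falls therefore depend on which clusters were summed. Vim, a filament of mesenchymal cells, had 25.0 CPM at 2 weeks and 367 and 414 CPM in the tumours (3.95, SE 0.664, edgeR adjusted p = 0.0217, 2 of 2 tumours). The matrix genes Fn1 (5.25, SE 0.945, edgeR adjusted p = 0.0272) and Tnc (4.90, SE 0.964, adjusted p = 0.0388) rose in 2 of 2 tumours. The mesenchymal list had 4 higher and 0 lower (7 and 0 adjusted over the list alone, median 1.40). Free RNA was not excluded, and Fn1 had 2559 CPM in fibroblast-like, 1034 in leukocyte-like and 410 in epithelial-like cells of tumour 1 (not scaled by TMM). Epcam, an epithelial adhesion molecule, had 1386 CPM at 2 weeks and 342 and 1364 CPM in the tumours.

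Sox10 (4.11, SE 0.689, edgeR adjusted p = 0.0214) and Mia (3.71, SE 0.742, adjusted p = 0.0404) rose in 2 of 2 tumours. The stem and neural crest list had 2 higher and 0 lower (4 and 0 adjusted over the list alone, 2.10). The mitochondrial clearance gene Bnip3 rose in 2 of 2 tumours (4.45, SE 0.769, edgeR adjusted p = 0.0238). The hypoxia and glycolysis list had 1 higher and 0 lower over all genes, and 12 and 0 adjusted over the list alone (2.23, percentile 100). MHC class I presentation had 0 higher and 1 lower (0 and 6 adjusted over the list alone, −1.59), with Psmb10 lower in 2 of 2 tumours (−2.74, SE 0.538, edgeR adjusted p = 0.0388). Interferon response had 0 past the test over all genes and 2 lower adjusted over the list alone (median −0.90). The inflammatory cytokine Il6 fell in 2 of 2 tumours (−4.24, SE 0.684, edgeR adjusted p = 0.0177) but had a log2 ratio of 1.71 in all cells that are not leukocyte-like. Il6 was also a leading gene of the 2 weeks basal-like cluster within its library and of an unnamed tumour 1 cluster (cluster 4 in each). Its NF-kB and inflammation list had 2 higher and 1 lower over all genes (6 and 1 adjusted over the list alone, median 0.12). The higher were Cxcl2 (5.19, edgeR adjusted p = 0.00977) and the cytokine Il1b (0 counts at 2 weeks, at least 62.4-fold, adjusted p = 0.0223), each in 2 of 2 tumours. Il1b was over 5 times higher in leukocyte-like cells. S phase (median −0.67) and G2 and M phase (−0.87) lists had 0 members past the test over all genes and 0 adjusted over the list alone (Rrm2 −1.91 and Top2a −2.03, missed).

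Against 2 weeks, 295 of 12439 genes passed edgeR (151 higher, 144 lower in tumours), 1952 at unadjusted p < 0.05, and 482 passed DESeq2. In luminal progenitor- or alveolar-like cells alone 37 passed edgeR, and the 2 weeks sum was mostly hormone-sensing-like, a subclass not named in the tumours. Of the 151 higher, 28 were over 5 times higher in leukocyte-like cells, such as the myeloid adaptor Tyrobp (0 counts at 2 weeks, at least 158.9-fold). The 2 weeks library held no named leukocyte-like cells, only 18 mixed cells, and free RNA from leukocytes in the tumour sums was not excluded.

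Against 5 months, milk genes were lower in the tumours. Csn2 fell from 19696 CPM to 4.74 and 0.466 (−12.88, SE 1.09, edgeR adjusted p = 0.00225, 2 of 2 tumours). Csn1s2a (−11.76, SE 1.65, edgeR adjusted p = 0.0192) and the milk-fat globule gene Btn1a1 (−8.23, SE 0.696, adjusted p = 0.00225) fell in 2 of 2 tumours. The peptide hormone gene Cck (at least 893-fold), Glycam1 (at least 507-fold) and Cxcl15 (at least 239-fold) fell to 0 counts in 2 of 2 tumours (edgeR adjusted p at most 0.00394). Rising in 2 of 2 tumours were Fn1 (6.32, SE 1.04, edgeR adjusted p = 0.0349), the basement membrane collagen Col18a1 (5.90, SE 1.03, adjusted p = 0.0465), the protease inhibitor Serpine2 (5.46, SE 0.770, adjusted p = 0.0195) and Cdkn2a (5.41, SE 0.737, adjusted p = 0.0166). Tagln (−4.66, edgeR adjusted p = 0.0195), Acta2 (−4.04, adjusted p = 0.0224) and Prlr (−3.11, adjusted p = 0.0433) fell in 2 of 2 tumours, but Tagln had 1.44 and Acta2 0.40 in all cells that are not leukocyte-like. The parotid secretory genes Dcpp2 (0 counts at 5 months, at least 46.9-fold) and Dcpp1 (8.82, SE 3.05, 1 count at 5 months) had larger values but missed the test, as did Vim (3.24), Top2a (4.06) and Ube2c (3.53).

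The milk list had 0 higher and 9 lower over all genes (0 and 16 adjusted over the list alone, median −2.55, percentile 0), and the hormone-sensing list 0 and 2 (0 and 5 adjusted over the list alone, −2.49). Basal genes had 0 higher and 4 lower (1 and 7 adjusted over the list alone, −2.12), and mesenchymal genes 1 and 0 (3 and 0 adjusted over the list alone, 1.47). The mesenchymal median was also above 0 in macrophage- or monocyte-like (1.55, percentile 100) and T cell-like cells (1.16, percentile 99.98). The basal median was 0.28 with the stricter cell filter. G2 and M phase genes had 0 past edgeR over all genes and 10 higher, 0 lower adjusted over the list alone (1.59, percentile 100), and the S phase list had 0 in either way (1.14, percentile 100). Interferon response had 0 in either way (−0.19), with medians of opposite sign in tumour 1 (0.48) and tumour 2 (−0.97). Dissociation and immediate early genes had 0 over all genes and 1 lower adjusted over the list alone (−1.23, Fos −2.18, missed). In all, 83 of 12439 genes passed edgeR (9 higher, 74 lower), 1232 at unadjusted p < 0.05, and 160 passed DESeq2. With the premalignant libraries as 1 group of 2, 0 genes passed edgeR and 1071 had unadjusted p < 0.05.

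The tumours were set against each other. Higher in tumour 1 were the imprinted RNA H19 (429 CPM against 4.43, log2 ratio 6.31), the stem and interferon surface gene Ly6a (6.18), the receptor kinase Met (744 against 17.7, 5.31), the matrix gene Postn (5.27), the adhesion protein Tes (4.84) and the caveolar coat gene Cav1 (4.33). Higher in tumour 2 were Dcpp2 (−6.72), Dcpp1 (−6.69), the actin-binding gene Pfn1 (−4.51), the Myc-linked RNA Pvt1 (−3.73), the lipid enzyme Gdpd3 (−3.55) and the monocyte attractant Ccl2 (−3.02). Pfn1 was low in leukocyte-like cells of tumour 1 as well (99.7 CPM against 2172 in tumour 2, not scaled by TMM), so its difference was not specific to epithelial-like cells. Pvt1 was carried by 28 cells of tumour 2 (cluster 7, 1056 CPM), and the other epithelial-like cells had 14.4 CPM. Interferon response had 8 of 19 members higher in tumour 1 and 0 lower (median 1.52, percentile 100, with the interferon-induced Rtp4 2.70 and Ifi27l2a 2.56). MHC class I presentation had 3 of 12 higher and 0 lower (0.73, Psmb9 2.13, the light chain B2m 1.21). NF-kB and inflammation had 2 higher and 6 lower of 18 (−0.54, the acute-phase gene Saa3 −3.76), and hypoxia and glycolysis 2 and 3 of 18 (−0.63, the oxygen sensor Egln3 −1.93). The p53 target list had 0 higher and 5 lower of 18 (−0.25, the death gene Pmaip1 −2.91, the cycle inhibitor Cdkn1a −1.55). Mesenchymal genes had 3 higher and 2 lower of 18 (1.00, Fn1 1.63, Tnc 1.61, the limb bud factor Prrx1 −3.21). Basal genes had 1 higher and 2 lower of 11 (Krt14 2.90, Krt17 −2.92), and epithelial junction and keratin genes 1 and 4 of 17 (Cldn4 −2.43, Epcam −1.99).

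In all, 1095 of 5760 genes were at least 2-fold apart, 692 higher and 403 lower in tumour 1, of which 19 and 15 were over 5 times higher in leukocyte-like cells. With library size scaling alone the split was 519 and 583 and the median shifted from 0.024 to −0.118, so the direction of moderate differences depends on scaling. This was 1 sample against 1 with no replicate check.

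In macrophage- or monocyte-like cells (394 cells at 5 months, 1809 and 281 in the tumours), the eosinophil-type ribonuclease Ear2 fell in 2 of 2 tumours (134 CPM to 1.30 and 0.994, −6.81, SE 0.427, edgeR adjusted p = 0.00582). So did the chromatin organiser Satb1, which also leads T cell-like clusters at 5 months (−5.90, SE 0.572, edgeR adjusted p = 0.0112), the sorting gene Vps37b (−3.45, SE 0.368, adjusted p = 0.0125) and the calcium-binding gene S100a4 (−3.12, SE 0.424, adjusted p = 0.0406). The folate enzyme Mthfd2 (−2.41, SE 0.353, edgeR adjusted p = 0.0465) and the early response factor Egr1 (−2.59, adjusted p = 0.0454) fell in 2 of 2 tumours. The membrane protein Tmem37 rose from 33.2 CPM to 251 and 266 (2.89, SE 0.439, edgeR adjusted p = 0.0499, 2 of 2 tumours). The arginase Arg1 (6.03, 3.61 CPM against 422 and 74.5) and Spp1 (3.68) had larger values but missed the test, as did the alternative-activation gene Retnla (−5.52). So did Saa3 (7.80, SE 1.66, 1 count at 5 months), Ifitm1 (4.83) and S100a8 (3.76), which lead neutrophil-like clusters in tumour 2. S100a8 was −3.01 and −3.12 with the looser and stricter cell filters. S100a4 and Arg1 were leading genes, within tumour 2, of the unnamed cluster of 230 cells nearest to macrophages (cluster 0). That cluster was not summed here, so the tumour 2 values of S100a4 and Arg1 also depend on which clusters were named. Interferon response had 0 past edgeR over all genes and 10 higher, 1 lower adjusted over the list alone (median 1.44, percentile 100, Ifi44 3.65, Irf7 2.24). The tumour-associated macrophage list had 0 and then 9 higher, 0 lower adjusted over the list alone (1.13), and hypoxia and glycolysis 0 and then 5 higher, 0 lower adjusted over the list alone (1.21, Bnip3 2.89, Tpi1 2.22).

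In macrophages, 58 of 8963 genes passed edgeR (4 higher, 54 lower), 1135 at unadjusted p < 0.05, and 104 passed DESeq2. Under other settings 2 genes passed edgeR with the looser cell filter, 2 with doublets kept and 0 at resolution 2.0 (969 at unadjusted p < 0.05), so the calls did not hold under these. Some of the 54 belong to other cells: Csn1s2a (−8.15, SE 0.567, 3 tumour counts) and Csn2 (−7.46) were over 5 times higher in epithelial-like cells, and Lef1 (−6.66) and Tcf7 (−5.80) are T cell factors. The T cell cytotoxicity (median −2.61, percentile 0) and regulatory T cell lists (−2.04, percentile 0.02) were low as well, with 0 past edgeR over all genes and 3 lower each adjusted over the list alone, so free RNA or mixed clusters at 5 months were not excluded.

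T cell-like cells were compared between 5 months (1968 cells) and the tumours (41 and 174 cells). The checkpoint receptor Pdcd1 rose from 46.8 CPM to 225 and 208 (2.36, SE 0.610, edgeR adjusted p = 0.0117, 2 of 2 tumours), and the granule gene Nkg7 from 158 to 942 and 630 (2.46, SE 0.676, adjusted p = 0.0224, 2 of 2 tumours). The checkpoint gene Lag3 passed (2.50, SE 0.627, edgeR adjusted p = 0.00769) but was higher in 1 of 2 tumours (10.9 CPM against 4.03 and 95.6). So was Cxcl10 (2.30, edgeR adjusted p = 0.0149, 290 and 1.57 CPM in the tumours). The co-stimulatory receptor Cd28 (−1.89, SE 0.535, edgeR adjusted p = 0.0315) and the naive T cell factor Lef1 (−2.27, SE 0.535, adjusted p = 0.00285) fell in 2 of 2 tumours. So did the phosphatase Dusp10 (−2.74, SE 0.546, edgeR adjusted p = 9.8e-05), Tcp11l2 (−2.76, SE 0.559, adjusted p = 0.000139), the actin regulator Fam101b (−1.98, SE 0.551, adjusted p = 0.0255) and the transcriptional regulator Cited2 (−1.96, SE 0.539, adjusted p = 0.0224). Lef1, Dusp10 and Fam101b were leading genes of a T cell-like cluster of 730 cells at 5 months (cluster 0). Their falls therefore also depend on which T cell-like clusters each library held. The exhaustion and checkpoint list had 2 higher and 0 lower over all genes and adjusted over the list alone (median 0.89, percentile 99.91). The cytotoxicity list had 1 and 0 (3 and 0 adjusted over the list alone, 0.63), and the regulatory T cell list 0 in either way (−0.62). The cytotoxicity median was −0.34 in tumour 1 and 0.81 in tumour 2. A cluster of 291 cells led by Gzma, Gzmb and Nkg7 at 5 months (cluster 7) was left unnamed for its NK cell genes, while the tumour 1 T cell-like cluster was led by Nkg7 and Xcl1, so the Nkg7 difference also depends on which clusters were named.

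In T cells, 91 of 6416 genes passed edgeR (73 higher, 18 lower), 455 at unadjusted p < 0.05, and 27 passed DESeq2. Most of the largest rises were of myeloid genes, such as Arg1 (0 counts at 5 months, at least 118-fold, 177 and 1.57 CPM in the tumours), the platelet factor Pf4 (7.41, SE 0.998, 1 count at 5 months), the chemokine Ccl17 (6.22), Fn1 (5.87), the complement gene C1qc (5.85) and S100a8 (5.34). A total of 47 genes passed when genes over 5 times higher in macrophages were left out. Free RNA from myeloid cells was not excluded.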

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

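No test in this part was chosen after its result was seen, and the unnamed clusters were found only once the cells had been grouped.

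The basal list had medians of opposite sign in 2 cell classes when tumours were set against 5 months. In T cell-like cells its median log2 ratio was 1.26 in tumour 1 and 1.03 in tumour 2, and in epithelial-like cells it was −2.86 and −2.00. The difference between the classes was not tested. Only 5 basal members were measured in T cell-like cells, and none passed the low-count filter, so a change in these cells is not shown.

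A total of 691208 UMIs in the 5 months library belonged to genes listed for that library alone, most of them immunoglobulin genes. They were left out because no other library lists these genes, and plasma cell-like and B cell-like cells were named without them.

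Unnamed clusters that belonged to no class of the marker table were not compared between libraries. At 2 weeks, 89 cells (cluster 6) carried embryonic stem cell genes. In tumour 1, 36 cells (cluster 17) were led by Cav1, Stmn2 and H19 and reached no lineage score over the minimum, with 918 CPM of Cdkn2a and 175 CPM of the chromatin protein gene Hmga2, and with 307 CPM of Krt8 but 3.02 CPM of Epcam. In tumour 2, 247 cells (cluster 5) carried the matrix genes Mgp (7269 CPM), Sparcl1 (810 CPM) and Col9a1 (332 CPM) with Sox10 (146 CPM), the cartilage gene Scrg1 (206 CPM) and Cdkn2a (593 CPM), but little Epcam (32.3 CPM), Krt8 (35.6 CPM) or Col1a1 (3.27 CPM). In comparison, Cdkn2a had 455 and 603 CPM in epithelial-like cells of tumours 1 and 2 and 23.02 CPM in fibroblast-like cells of tumour 1. These CPM are not scaled by TMM. The origin of the tumour 2 cells was not tested, and it stays open. The rule for a sample that departs from its replicates needs more replicates than were present.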

How the results depend on the processing

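Of the alternatives below, hormone-sensing-like cells only, leaving out ribosomal protein genes low at 2 weeks, and leaving out macrophage genes for T cells were chosen after the data were seen, and all others before.

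The data have 2 tumour replicates, 1 library per premalignant time point and different sorts per stage, so time, sort and library cannot be separated, and no count below tests that. No paired analysis was possible because the labels link no animal to more than 1 library. T cell-like cells gave no comparison under the looser cell filter or with doublets kept, because tumour 1 then held 0% T cell-like cells. The cause of each changed result was not tested. Each result was counted once per alternative setting, so the next numbers are pairs of a result and a setting. Of the pairs for counts and shares, 190 stayed and 100 moved. Of the pairs for named genes, 1926 stayed, 180 weakened, 87 strengthened, 21 reversed and 13 moved. Of the pairs for list medians, 1344 stayed, 89 strengthened, 67 weakened and 7 reversed.

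For tumour against 2 weeks (295 genes with edgeR), 1104 passed without the low-count filter, 482 with DESeq2, 0 with the premalignant libraries as 1 group, 37 in luminal progenitor- or alveolar-like cells only, 502 with doublets kept and 455 at resolution 2.0. For tumour against 5 months (83), 137 passed with library size only, 537 without the filter, 160 with DESeq2, 0 with 1 premalignant group, 52 in luminal progenitor- or alveolar-like cells only, 55 in all cells that are not leukocyte-like, 127 with the looser cell filter, 150 with doublets kept and 130 at resolution 2.0. For macrophages (58), 34 passed with DESeq2 size factors, 26 with library size only, 608 without the filter, 104 with DESeq2, 2 with the looser and 15 with the stricter cell filter, 2 with doublets kept, 97 at resolution 0.5 and 0 at resolution 2.0 (969 at unadjusted p < 0.05). For T cells (91), 27 passed with DESeq2 and 47 without macrophage genes. Genes at least 2-fold apart numbered 769 without tumour 1 and 1846 without tumour 2. For 5 months against 2 weeks (1663), 515 genes were apart at 100 CPM and 4153 with no CPM minimum, and for tumour 1 against tumour 2 (1095) 317 and 2750. The share of these that was higher at 5 months moved from 51.7% to 62.0% in luminal progenitor- or alveolar-like cells and 39.25% in hormone-sensing-like cells. With library size only it was 42.75%, and the share higher in tumour 1 moved from 63.2% to 47.1%.

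With the stricter cell filter, epithelial-like shares were 94.8% at 2 weeks, 15.3% at 5 months and 8.73% in tumour 1, and leukocyte-like shares 83.8% at 5 months, 82.7% in tumour 1 and 48.3% in tumour 2. With the looser filter, epithelial-like shares were 11.8% at 5 months and 30.4% in tumour 2, and the leukocyte-like share 87.6% at 5 months. Unnamed shares were 5.25% at 2 weeks, 1.43% in tumour 1 and 24.9% in tumour 2 (stricter), 17.6% in tumour 2 (looser), 1.35% in tumour 1 (resolution 0.5) and 9.54% in tumour 2 (resolution 2.0). Fibroblast-like cells of tumour 1 were 5.96% (stricter) and 5.54% (resolution 0.5).

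Among epithelial-like cells at 2 weeks, luminal progenitor- or alveolar-like cells were 18.4% (stricter), 0% with doublets kept, 0% at resolution 0.5 and 5.30% at resolution 2.0, so that class was not stable there, while hormone-sensing-like cells were 77.3% (stricter). The former were 84.7% at 5 months (looser), and in tumour 2 92.9% (looser), 92.7% with doublets kept and 100% at resolution 0.5. Among leukocyte-like cells at 5 months, T cell-like cells were 53.1% (looser), 29.2% (stricter) and 52.6% (resolution 2.0). In tumour 1 they were 0% with the looser filter and 0% with doublets kept. Macrophage- or monocyte-like cells at 5 months were 8.92% (looser), 17.2% (stricter), 8.70% with doublets kept and 8.76% at resolution 2.0. They were 87.1% in tumour 1 (resolution 0.5), and in tumour 2 52.1% (looser), 54.5% (stricter), 56.1% with doublets kept and 47.1% at resolution 2.0. B cell-like cells were 6.39% (stricter) and 18.1% (resolution 0.5) at 5 months, and in tumour 2 0% (looser), 0% (stricter), 0% with doublets kept and 0% at resolution 0.5. Dendritic cell-like cells at 5 months were 21.4% (stricter) and 7.59% with doublets kept, and neutrophil-like cells of tumour 2 6.39% (stricter) and 22.0% (resolution 2.0).

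Keratin co-detection was 2.56% at 2 weeks and 9.05% in tumour 1 at 1000 UMIs, 20.05% in tumour 1 at 3000 UMIs, and 5.60%, 7.16%, 34.2% and 6.67% in the 4 libraries with no thinning. The proliferating call was 32.7%, 4.63%, 18.1% and 14.0% at 1000 UMIs, 60% at 2 weeks, 17.9% at 5 months and 35.4% in tumour 2 at 3000 UMIs, and 58.5%, 29.7%, 77.0% and 64.7% with no thinning. With the stricter filter it was 52.0% at 2 weeks.

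In hormone-sensing-like cells only, 5 months against 2 weeks reversed for Ehf (−1.05), Sox10 (−0.56), Foxc1 (−0.77) and Hk2 (−1.13), and for the hormone-sensing luminal list (median 0.98) and the NF-kB and inflammation list (−0.16). Col3a1 reversed to 0.59 in luminal progenitor- or alveolar-like cells only, 2.34 in hormone-sensing-like cells only and 1.57 in all cells that are not leukocyte-like. In that last population, tumour 1 against tumour 2 reversed for Ccl2 (0.45), Prrx1 (0.89) and the basal list (0.50), tumour against 2 weeks for Tagln (1.499) and Il6 (1.71), and tumour against 5 months for Tagln (1.44) and Acta2 (0.40). With 1 premalignant group, Spp1 (−0.64), Ier3 (−0.17), Top2a (−1.08) and Ube2c (−0.14) reversed. The basal list reversed against 2 weeks in luminal progenitor- or alveolar-like cells only (1.09) and against 5 months with the stricter filter (0.28). In macrophages, S100a8 reversed with the looser (−3.01) and stricter filter (−3.12), and the epithelial junction and keratin list with the stricter (0.13). Leave-one-out log2 ratios in T cells ranged from 2.13 to 2.24 for Pdcd1, from 1.99 to 2.57 for Nkg7, from −1.24 (without tumour 2) to 3.02 for Lag3, and from −3.62 (without tumour 1) to 3.20 for Cxcl10. The T cell cytotoxicity list ranged from −0.34 (without tumour 2) to 0.81 (without tumour 1).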

Other observations

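Of the weighed explanations, doublets, a change in the epithelial-like cells, lower ribosomal protein counts as a whole, and the strain test over all genes of the segment were written after their result was seen, and the others before.

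The values describe epithelial cells that were mostly hormone-sensing-like and cycling-gene-rich at 2 weeks, milk-gene-rich with high Sox10 at 5 months, and Cdkn2a-rich with high Sox10 in tumours. Cdkn2a was also higher in tumours than at 5 months when only luminal progenitor- or alveolar-like cells were compared, where 52 genes passed edgeR.

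Cells with embryonic stem cell genes appeared in the 2 weeks library: 89 cells with 4463 CPM of Dppa5a and 835 CPM of Pou5f1, against 5.79 and 2.62 CPM in epithelial-like cells. Krt8 had 18.98 CPM in them. At the thinned depth 5.88% carried a Krt8 or Krt18 UMI, against 96.5% of epithelial-like cells, which argues against doublets. A Y-linked UMI was present in 6.74% (2.51 to 14.1) of them against 0.17% (2 of 1179, up to 0.611%) of epithelial-like cells, and Xist in 3.37% against 96.1%. The share with a Y-linked UMI lay above the upper bound in epithelial-like cells, but the rule asked for most cells to carry one. By that rule, set beforehand, male cells from another source and cells of the female mice in another state cannot be told apart. No further origin was weighed.

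Ribosomal protein genes with few counts at 2 weeks numbered 13 of 81, against 0 in each other library. Rps18 (chr17:33951999-33956001) had 375 CPM against at least 2839 in epithelial-like cells of the other libraries. Their 3' ends shared more 60-mers with other genes than random sets of the others did (median 63.7% against 21.6%, percentile 99.47), as reads shared with near-identical copies would predict. Of the 13, 12 were also low in the cells with embryonic stem cell genes (the exception was Rps18 with 4117 CPM), which argues against a change in epithelial-like cells, and the other ribosomal protein genes had a median log2 ratio of 0.205, which argues against a loss as a whole. Why only this library was affected stays open.

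Adjacent chromosome 6 genes led tumour 1 clusters, among them Met (chr6:17463800-17573980), Tes and Cav1. The segment's 10 other genes (chr6:13867735-24665009) had a median log2 ratio of 2.60 over tumour 2, all 10 above 0, at percentile 100 of 5452 windows, which is consistent with a gain of the segment and could also stem from regulation, which was not tested. A library or strain difference predicted the same in leukocyte-like cells. The test as first stated left 1 gene (−0.328). Over 9 genes of the segment, the leading ones included, the median was 0.187 against 3.69 in epithelial-like cells. The leading genes were picked as high in those tumour 1 clusters against all other clusters, the leukocyte-like clusters of tumour 1 included. The 3.69 is therefore high by selection, and genes also high in tumour 1 leukocyte-like cells were less likely to be picked. These 9 genes were little changed in leukocyte-like cells, but the comparison cannot decide on a library or strain difference. In the 36 unnamed cells of tumour 1 (cluster 17) the segment's other genes had a median of 1.62 over fibroblast-like cells. Of 9 such genes 7 were above 0, and the median lay at percentile 99.09, as the same gain would predict. Regulation was not tested here either. Cluster 17 was itself among the clusters that gave the leading genes, which this median leaves out.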
